A study of Arabidopsis thaliana with 4 samples.

How the data were processed

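Transcript levels were measured on 1-colour Agilent oligonucleotide arrays in 4 total RNA samples of Arabidopsis thaliana, 2 from Col-0, the reference accession, and 2 from ica, described by its submitters as a transgenic Col-0 line that overexpresses AT5G40830 (ICA). Per the labels' protocols, RNA came from the inflorescence stem of soil-grown plants when the 6th silique was developing, and the labels give the sampled part as the top 1 cm of the vegetative nodes. Plants had 16 h of light and 8 h of dark at 23 °C. Each sample was hybridised to 1 array with Cy3 dye. Samples were grouped by their titles. The labels number the replicates 1 and 2 in each genotype and do not say whether they came from separate plants or growth batches, so p-values measure only the spread between these samples, which may be technical.

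Per the file headers, the 4 arrays lay on 1 slide of design 031025, were scanned in a single channel and were read with Feature Extraction 10.7.1.1. The deposited intensity values are that software's processed signal, which is background-subtracted and detrended within each array and not normalized between arrays, and the median brightness of each spot and of its local background. The authors' deposited value table holds log2 values with no header. Set against the scanner values spot by spot, each of its columns ranked the spots as the median signal of the same array did (Spearman rho 1 on every array) and less closely as the processed signal (rho from 0.987 to 0.991). Its columns had medians of 9.041, 9.039, 9.041 and 9.044 and the same highest value of 18.796, as after quantile normalization without background subtraction. The distribution it was normalized to is not given in the sources used here. Whether the deposited table was centred beyond that stays unknown.

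The files name probes by Agilent identifier only, and do not pair them with genes. No table used here makes that pairing. The transcript of ICA, its chromosomal neighbours (5 loci planned on each side), and the 44 gene lists and families fixed before the data were examined (33 lists with 407 entries and 11 families defined by description) could therefore not be looked up and are not analysed here. Counts below are of probes where the plan had genes, and several probes can belong to 1 gene. The choices that follow were made before the data were examined unless stated otherwise.

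From the processed signal, log2 values were taken and each array's 75th percentile over its non-control spots was subtracted. Control spots and spots flagged as non-uniform or population outliers were left out, and the spots of a probe were averaged. A probe was tested when it was well above background, by the scanner software's flag on at least 1 of its spots, on both arrays of at least 1 genotype. Of 43603 probes, 43557 had a value on all arrays, and 31040 of them (71.3%) passed that filter. The 12517 dim probes were not tested. ica and Col-0 were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are given as ica minus Col-0. A probe not well above background on any array of a genotype has only a bound there. Its fold is then given as "at least", from the brighter genotype's mean against the dimmer genotype's mean of, per array, the higher of the probe's own signal and the lowest signal well above background. A probe can read above that lowest signal without the flag, so these bounds are approximate.

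The rule for single items named up to 10 genes each way by fold change, among those past the threshold with non-overlapping genotypes. Without gene names only the 2 most extreme probes each way by fitted fold are named. The alternatives tried were quantile normalization, a median shift, no filter on dim probes, a filter on all 4 arrays, a trended and robust variance prior, the replicate number as a block, the deposited value table, other thresholds and leaving out each array in turn. Normexp background correction had been planned on the mean signal, a column the files used here do not hold, and was run with an offset of 50 on the median signal. Scaling to spike-in probes, a crossed block and a second detection flag were also added after the data had been seen. The test was tried on simulated data for the same 31040 probes. Errors were independent, drawn from the fitted spread, alike in both genotypes and unrelated to signal. Of 50 probes changed 2-fold 0 were called, and of 50 changed 4-fold 13. Of 50 changed 16-fold 40 were called and of 50 changed 64-fold 49, with 5 false calls. No other probe was changed, and the adjustment is stricter when few are. In the data, 615 of the 3299 probes that passed changed by less than 2-fold, so these shares do not carry over to it. With 11346 probes changed by the folds fitted to the data, 5609 of them were called, with 164 false calls (2.84% of all calls). That run took every probe at an unadjusted p below 0.05 as changed, and called more probes than the 3299 of the data. In the data the ica arrays varied more (median SD 0.19 against 0.11 in Col-0). The share of false calls therefore holds for the simulation only. The 2 arrays per genotype limit the precision.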

Results

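Gene expression in the inflorescence stem was compared between Col-0 and ica, to find transcripts whose level differs in the ica line. Its submitters describe ica as a transgenic line overexpressing the Arabidopsis gene AT5G40830, which could not be checked here. The comparison rested on 2 arrays per genotype. Between 69.1% and 72.6% of the 61657 probe spots of an array were well above background, and no spot was saturated. Brightness differed between arrays. The 75th percentile of the processed signal was 2477 and 1483 on Col-0 replicates 1 and 2, and 3959 and 1587 on ica replicates 1 and 2.

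The genotypes differed more than the replicates did. Over the 31040 tested probes, the log2 difference between the Col-0 arrays had an SD of 0.40, and that between the ica arrays an SD of 0.56. Between arrays of opposite genotype the SD lay between 0.85 and 1.13. Duplicate spots of the same probe on 1 array differed with an SD of 0.15 to 0.23, where both were well above background. This covers noise between the spots of 1 array and leaves out technical error between arrays. A difference above 2-fold was seen for 2.50% of probes between the Col-0 arrays, for 7.93% between the ica arrays and for 13.9% to 22.1% between arrays of opposite genotype. The first principal component held 80.3% of the variance and separated the genotypes, with scores of -67.2 and -96.1 for Col-0 and 66.0 and 97.3 for ica.

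Of the tested probes, 3299 (10.6%) passed the threshold, 1826 higher and 1473 lower in ica (limma, Benjamini-Hochberg adjusted p below 0.05). The median change was 3.06-fold among the higher probes and 2.41-fold among the lower ones. The higher side reached further. Among the probes that passed and were well above background on every array, 404 were at least 4-fold higher and 130 at least 4-fold lower in ica, and 71 were at least 16-fold higher and 4 at least 16-fold lower. By the fitted fold of all probes that passed, which overstates what was measured where a genotype was not above background, the 16-fold counts were 185 and 17. The smallest change that passed was 0.71 on the log2 scale. Another 2211 probes differed by at least 2-fold without passing. At an unadjusted p below 0.05 there were 11346 probes. The genotypes' values did not overlap for 69.5% of the tested probes, where chance gives 33.3% for 2 arrays against 2. The median over all tested probes was -0.06 on the log2 scale.

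**Figure D1:**
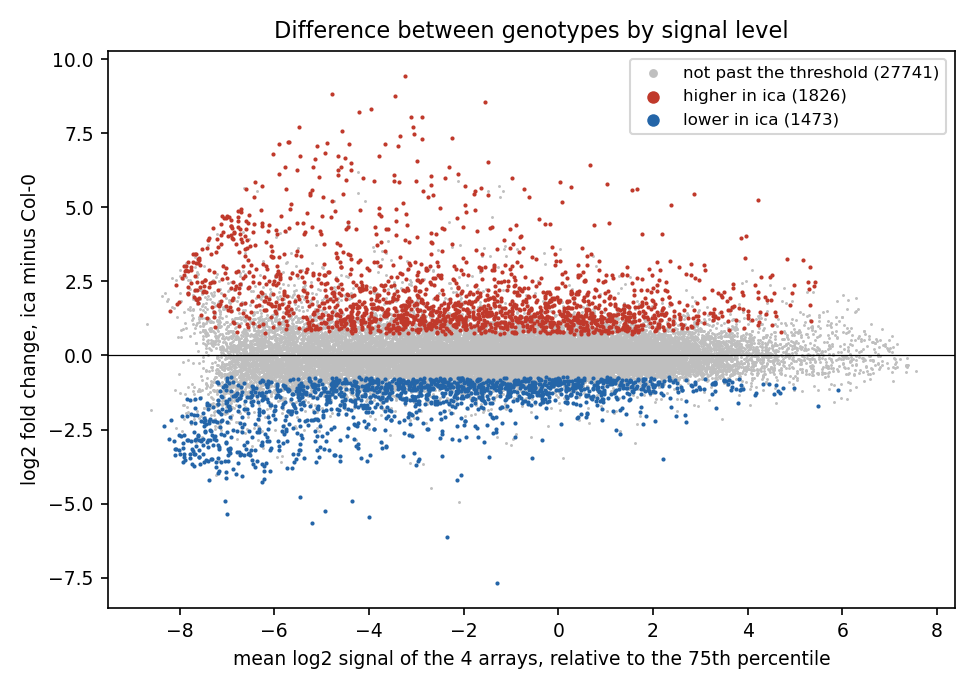
Fold change of each tested probe (log2, ica minus Col-0) against its mean log2 signal over the 4 arrays relative to the 75th percentile. Red points are the 1826 probes higher in ica and blue points the 1473 lower, at an adjusted p below 0.05, and the red points, drawn at fitted folds, extend further from 0 than the blue ones.

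The number of probes past the threshold depended on the filter, the threshold, the variance prior, the values used and single arrays. It was 0 without the filter on dim probes (9216 at an unadjusted p below 0.05), and at an adjusted p below 0.1 there were 4257 higher and 4515 lower probes. It was also 0 when either Col-0 array was left out (6655 and 4824 probes at an unadjusted p below 0.05 without Col-0 replicates 1 and 2), 700 without ica replicate 2 and 5378 without ica replicate 1. In these fits the spread between replicates came only from the genotype that kept both arrays. It was wider in ica (median SD 0.19) than in Col-0 (0.11). The counts without 1 array therefore also reflect which genotype kept both arrays. With a trended and robust variance prior 3141 were higher and 2935 lower, and with the authors' deposited log2 values 3027 and 2831. Quantile normalization (2307 higher, 1914 lower) and a median shift (1932 higher, 1730 lower) left the split of calls about as it was. Spike-in scaling, which moved the median of all probes to 0.61, gave 1960 higher and 224 lower probes. The shift came mostly from ica replicate 1, which lay 1.37 log2 units above the lowest array relative to the spike-ins. That fit gave every probe the same spread (infinite prior degrees of freedom, against 2.29 in the main fit). Its counts are therefore not comparable with the others. Normexp correction, which also replaced the processed by the median signal, gave 96 higher and 13 lower.

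Changed probes were found at every signal level. Of the 29182 probes well above background on every array, 1510 were higher and 1169 lower in ica (9.18% together). In the dimmest quartile of these by mean signal 419 were higher and 435 lower, or 11.7%, and in the brightest 323 were higher and 192 lower, or 7.06%. The median SD between replicates was 0.15 in the dimmest and 0.09 in the brightest quartile in Col-0, and 0.28 and 0.15 in ica. The other 1858 tested probes were dim on at least 1 array, and 620 of them passed (33.4%), but the filter admits such a probe only when 1 genotype is bright on both arrays.

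Some transcripts were measured in 1 genotype alone. On both ica arrays and neither Col-0 array, 442 probes were well above background, and 207 of them passed the threshold as higher in ica. The reverse held for 256 probes, of which 160 passed as lower in ica. These counts depended on which arrays were read. The 442 and 256 probes became 994 and 419 without Col-0 replicate 1, and 1095 and 307 without ica replicate 2. Without Col-0 replicate 2 they became 488 and 678, and without ica replicate 1 they became 568 and 767. The excess toward ica therefore reversed when either of these last arrays was left out. By the 75th percentile, Col-0 replicate 2 was the dimmest array (1483) and ica replicate 1 the brightest (3959). An effect of brightness on these counts was not tested. Among the 207 probes, 101 were at least 4-fold and 24 at least 16-fold higher in ica. Among the 160 probes, 43 were at least 4-fold and 1 at least 16-fold lower. Not being well above background sets a limit from the array's sensitivity and does not show that a transcript was absent.

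The probes with the most extreme fitted changes had these values, with log2 signals relative to the 75th percentile of each array. This ranking includes probes not measured on every Col-0 array. Among probes that passed and were measured on all 4 arrays, the highest fold toward ica was 379. Probe A_84_P854454 stood at 1.49 ± 1.36 (SD, n = 2) in ica and -7.95 ± 1.35 (SD, n = 2) in Col-0, where it was well above background on 1 of 2 arrays. Its fitted log2 fold change, which rests in part on that signal near background, was 9.43 with a standard error of 0.93 (limma, adjusted p = 0.0263). Probe A_84_P172991 stood at -0.38 ± 0.19 (SD, n = 2) in ica and was not well above background on either Col-0 array, where its mean signal was -9.20. Its fitted log2 fold change, which rests on that Col-0 signal, was 8.83 with a standard error of 0.26 (limma, adjusted p = 0.0166). As a bound on the processed signal, which was not itself tested, the probe was at least 109-fold higher in ica. Its log2 fold changes with normexp correction (4.41) and the deposited values (5.78) lay below that bound. Probe A_84_P761415 fell from 2.54 ± 0.07 in Col-0 to -5.12 ± 0.29 in ica (SD, n = 2 each). This is a log2 change of -7.67 with a standard error of 0.20 (limma, adjusted p = 0.0166), and the probe was well above background on all 4 arrays. Probe A_84_P704429 fell from 0.71 ± 0.94 to -5.41 ± 1.61 (SD, n = 2 each), a log2 change of -6.12 with a standard error of 0.91 (limma, adjusted p = 0.0365). None of the 4 passed when either Col-0 array was left out or without the filter on dim probes. A_84_P854454 and A_84_P704429 also missed the threshold without ica replicate 2 (limma, adjusted p = 0.0516 and 0.0552) and with normexp correction (0.0546 and 0.0544).

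**Figure D2:**
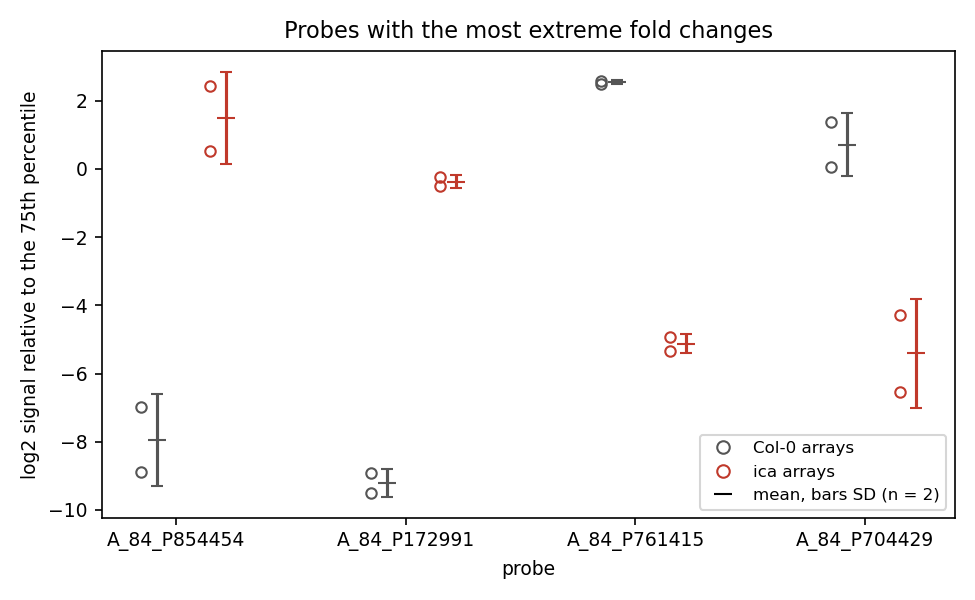
Log2 signal relative to the 75th percentile for the 4 named probes. Open circles are single arrays of Col-0 (grey) and ica (red), with the mean and SD of n = 2 beside them, and the genotypes of each probe do not overlap.

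The contrast between the genotypes was wider for the arrays numbered 2 than for those numbered 1. The log2 difference between ica and Col-0 had an SD of 1.13 for replicate 2 and 0.85 for replicate 1. No label pairs these numbers across genotypes, and the crossed pairs lay between. The SD was 0.98 for Col-0 replicate 1 with ica replicate 2 and 0.99 for Col-0 replicate 2 with ica replicate 1. Of the 3299 probes past the threshold, 2542 (77.1%) differed more between the replicate 2 arrays. Across probes, which are not independent replicates, the 2 contrasts correlated at Pearson's r = 0.77.

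**Figure D3:**
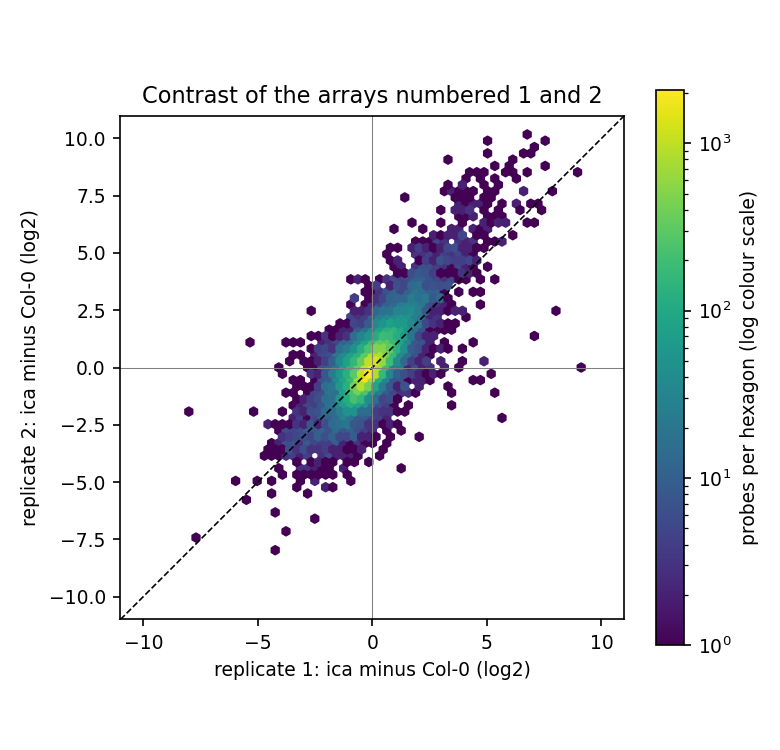
Log2 difference between ica and Col-0 for the replicate 1 arrays (x axis) and the replicate 2 arrays (y axis) over the 31040 tested probes, coloured by the number of probes per hexagon on a log scale. The dashed line marks equal differences, and the probes spread further along the y axis, with an SD of 1.13 against 0.85.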

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

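The tests of explanations below were chosen after the results they concern had been seen, except the first version of the mixture test.

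Among the 12 ERCC and 13 ETG control probes, 2 were well above background on most of their spots on at least 1 array. The negative controls had median log2 signals of 1.57 to 1.82. The ERCC-00104_60 probe was well above background on most of its 35 spots on Col-0 replicate 1, with a median log2 signal of 4.74, and on ica replicate 1, with 4.06. On Col-0 replicate 2 it stood at 3.497 with 37.1% of its spots well above background, and on ica replicate 2 at 2.39 with 0%. The highest negative control spot reached 3.94 on Col-0 replicate 1, 3.42 on Col-0 replicate 2, 4.80 on ica replicate 1 and 2.9996 on ica replicate 2. The ETG10_236652 probe was well above background on most of its spots on Col-0 replicates 1 and 2, with 4.43 and 3.99, and on ica replicate 2, with 4.65. On ica replicate 1 it stood at 1.95 with 0% of its spots well above background.

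In all, 3299 probes passed the threshold in a design of 2 arrays per genotype. The Col-0 arrays lay at positions 1 and 2 of the slide and the ica arrays at positions 3 and 4. A steady trend along the slide would carry the step between neighbouring arrays of 1 genotype along with the genotype contrast, at a slope of 0.5. The slope over the tested probes was -0.00371, with a 95% bootstrap interval from -0.0105 to 0.00360. That interval resamples probes, which are not independent, and each genotype gave only 1 step. On the first principal component the steps ran opposite ways, from -67.2 to -96.1 in Col-0 and from 66.0 to 97.3 in ica. The slope averages these 2 steps. A steady trend would carry both the same way, so these values argue against it as the whole cause. A gap in brightness is argued against as the source of the contrast by the opposite-genotype pair closest in brightness, the replicate 2 arrays. They lay 0.10 apart on the log2 scale at the 75th percentile. Their contrast was the widest, an SD of 1.13 against a mean of 0.94 for the other 3 pairs. This is 1 pair of arrays, and these were the 2 dimmest. An effect of low brightness on the width of the contrast is therefore not excluded. A sudden step between positions 2 and 3, or a difference in harvest, coincides with genotype and cannot be told apart from it, and the genotype itself stays untested as an explanation.

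The wider contrast of the replicate 2 arrays has 2 technical explanations that were tested. Both replicate 2 arrays were also dimmer than both replicate 1 arrays (75th percentile 1483 and 1587 against 2477 and 3959). Brightness was not tested as a cause of this width. Signal compression on the replicate 1 arrays would need a flatter response by about the ratio of the contrasts, which was 1.33. The slopes of the 8 detected E1A spike-in probes on the replicate 1 arrays were 0.985 ± 0.019 (SD over 4 array pairs) of those on the replicate 2 arrays. The 4 ratios share the same 4 slopes. Over the log2 signals of these probes, 6.18 to 18.61, this argues against compression. Dimmer signal was not covered. A mixture of RNA would need 8.51% of the other genotype in both replicate 1 samples and would hold every strongly changed probe above that level. The test was changed after its first version had been seen. That version took probes over 100-fold apart and not well above background on the dim side, and asked whether the upper quartile lay below 8.51%. It had 50 probes for Col-0 replicate 1, with a median of 2.56% and an upper quartile of 5.26%, but 1 probe for ica replicate 1, so it decided nothing for both samples together. In the version used, a wider choice of probes was set against the lower quartile, since a mixture sets a floor under all of them, and by the first criterion this choice would have decided nothing, with an upper quartile of 9.94% for Col-0 replicate 1. For 176 probes over 32-fold higher in ica on the replicate 2 arrays, Col-0 replicate 1 carried a median of 6.04% of the ica replicate 1 signal, with a lower quartile of 2.85%, which argues against ica RNA in the Col-0 sample as the whole cause. The reverse test had 13 probes, with a median of 7.46% and a lower quartile of 4.996%, too few to decide for ica replicate 1, and a difference between the plants sampled stays open.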

How the results depend on the processing

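With normexp on the median signal, 3268 of the 3299 probes past the threshold kept their direction. Filters, variance priors, blocks and thresholds leave fold changes as they are. The 1826 higher and 1473 lower probes became 0 and 0 without the filter on dim probes (9216 at an unadjusted p below 0.05), 96 and 13 with normexp on the median signal, 3141 and 2935 with a trended and robust variance prior, 3027 and 2831 on the deposited log2 table, and 4257 and 4515 at an adjusted p under 0.1. With the replicate block they became 683 and 382, of which 992 were among the main calls, and A_84_P704429 no longer passed (limma, adjusted p = 0.0547). The numbers do not pair the samples by any label, and their deviations correlated at -0.106 over probes. A block with the numbers crossed gave 1716 and 999. Spike-in scaling left 224 lower probes, beside 1960 higher, in a fit that gave every probe the same spread. Leaving out 1 array gave 0 to 2923 higher and 0 to 2455 lower probes, with the lone array assumed to vary like the other genotype. Quantile normalization, a median shift, the filter on all 4 arrays and a 2-fold minimum stayed within 1.5 times the counts. Leaving out 1 array gave 488 to 1095 probes on in ica and off in Col-0, and 307 to 767 the other way, against 442 and 256. The larger count was on the Col-0 side without Col-0 replicate 2 and without ica replicate 1. The 4 named probes passed the threshold in 37 of 54 fits. Their log2 fold changes ranged from 6.10 to 10.39, 4.41 to 9.50, -7.87 to -6.74 and -7.26 to -4.79, and the adjusted p (limma) reached 0.152, 0.144, 0.144 and 0.205 for A_84_P854454, A_84_P172991, A_84_P761415 and A_84_P704429. A_84_P172991 was not well above background in Col-0, so its fold changes are fitted values only. With normexp (4.41) and the deposited values (5.78), both on the median signal, they lay below its 109-fold bound, which was set on the processed signal. The causes of these shifts were not tested. Averaging the probes of a gene, the gene list tests and the fit for ICA were not run, since the probes carry no gene names here. Signal near background limits the dimmest probes, whose replicates varied most.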

Other observations

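The long tail of large increases was not matched by decreases under any scaling tried. Among probes well above background on every array, 77 were at least 16-fold higher and 5 at least 16-fold lower in ica by fitted fold change, whether or not they passed the threshold. With quantile normalization the counts were 73 and 5, with the deposited values they were 47 and 2, and with spike-in scaling 121 and 2. Without ica replicate 1 they were 108 and 14, and without Col-0 replicate 2 they were 58 and 4. The highest fold among probes past the threshold and measured on all 4 arrays was 379-fold toward ica and 203-fold toward Col-0.

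Relative to the E1A spike-in probes, the 75th percentile of ica replicate 1 lay 1.37 log2 units above that of Col-0 replicate 2, the lowest array. Col-0 replicate 1 lay 0.14 and ica replicate 2 lay 0.11 above it. A shift of that size was seen on 1 of the 2 ica arrays. The amount of spike-in added per sample is not given in the sources used here.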
